A study of Debaryomyces hansenii with 6 samples.

How the data were processed

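The study hybridised amplified RNA from Debaryomyces hansenii to 6 Agilent 2-colour arrays. Cells had grown in rich medium and were exposed to 2 M NaCl for 0.5, 3 or 6 h, and the control was an aliquot taken at time 0, per the labels. Per the series design, replicate 1 carried the control in Cy3 and the stressed RNA in Cy5, and replicate 2 exchanged the dyes and used different biological replicates of both RNAs. Dye orientation and biological replicate are therefore the same split of the arrays. All 6 arrays lay on 1 slide and were scanned once, in 2 rows of the slide that match the 2 replicates, so slide and scan gave no batch to separate.

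The spot intensities were extracted with Feature Extraction 9.1.3.1, per the file headers. The deposited intensities are pixel medians and means of spots and local background, together with processed signals. The log10 ratios in the files are of processed red over processed green signal, per the file headers. The deposited table of the series holds log2 ratios of stressed over control, for which the submitters' processing notes name limma. The authors used median intensities, per the labels. The log2 scale and direction of the deposited table were found by comparison with the scanner signals. Its columns correlated at r = 0.99 or above with signals that had loess but no background correction, averaged over a gene's probes, and its column medians were -0.00121, 0.00381 and 0.0106 for replicate 1 at 0.5, 3 and 6 h and 0.00289, -0.0109 and 0.00272 for replicate 2. The exact normalization behind it is not given in the sources used here.

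Median signals were background-corrected with normexp at an offset of 50 and normalized by loess within each array in limma 3.58.1 (R 4.3.3), with control spots at weight 0. Spots marked as outliers were left out, 16 values among the probes used. Ratios were turned so that positive values mean higher in the stressed RNA than in the time-0 control. Before turning, arrays of opposite dye orientation correlated negatively and arrays of one orientation positively across genes. Probes were kept when well above background in at least 2 of 12 channel values, which left 11721 probes and 5966 genes, and a gene was represented by its brighter probe. One fit over the 6 arrays gave a coefficient for each of the 3 times, tested with lmFit and eBayes at a Benjamini-Hochberg adjusted p of 0.05. Deviations of same-numbered arrays correlated across genes at 0.19, 0.31 and 0.37 for the 3 pairs of times, which a shared culture or control or a dye bias would each give, and the labels do not say which arrays share a culture or control. The fit fixed before the data were examined had no replicate block, and the counts with one are given beside it. No dye term was used in that fit, since it would also take up the difference between the biological replicates. Ratios were computed against local background, whose median was lower than the signal of the negative controls on each array, and the spike-in ratios spanned less than after subtraction of the negative controls. By the scanner software's flag for signals well above background, no named locus was dim in a whole group, so no fold is given as a bound. Dimness was not judged against the negative controls. After normalization, with the offset included, the log2 control signal of DEHA2A03498g was 6.41 at 3 h. For DEHA2C03476g at 0.5 h the stressed signal was 7.09 and the control signal 7.19. Ratios of such dim loci may be compressed, which was not tested. At 3 h the control of DEHA2A03498g, DEHA2C03476g, DEHA2C07370g, DEHA2G03322g and DEHA2E06908g was well above background on 1 of 2 arrays, so their 3 h ratios are less certain.

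The array files give accessions in place of gene names and the description "Unknown" for each gene. Unversioned accessions were matched to locus names in the reference table of assembly ASM644v2, for 5348 of 6320 genes, and for 5120 of the 5966 tested. The array files name no assembly, so no coordinates are given, and the table was used for names and for the order of neighbouring loci. The 29 gene lists fixed beforehand consist of gene symbols. No symbol could be matched to the accessions of the array through the tables used here, so the list tests and their alternatives were not run. The rule for named genes, fixed before the data were examined, was the 6 highest and 6 lowest called genes per time with a description and the same sign on both arrays, 4 and 4 per difference between times, and by locus 1 highest and 1 lowest per time of the genes without one. Where none passed, it took 4 and 4 by moderated statistic. Since no gene had a description, the fixed rule left 1 highest and 1 lowest locus per time. The other loci were named by the same ranks with the description condition dropped, a choice made after the values were seen. Genes without a locus name stayed in the tests and counts but were not named, so the ranks hold among genes with one.

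Probe sequences were compared with each other with BLAST+ 2.17.0, and 93 genes had a probe with at least 50 bases identical to a probe of another gene. The fit was tested on simulated data of 5966 genes with 200 changed at 0.5 h. It called 4.48% of genes changed by a log2 ratio of 0.5, 67.2% of those changed by 1 and 97.0% of those changed by 2. Of its 119 calls at 0.5 h, 7 were false. For a log2 ratio of 1 the share called was 62.7% at 3 h and 55.2% at 6 h. The adjusted threshold depends on how many genes change. The data gave 4 calls at 0.5 h, so these shares do not carry over to the data. The test of neighbouring loci recovered a simulated correlation of 0.4 as 0.38 over 5120 loci. Alternatives covered background correction, mean signals, processed signals, normalization, filters on dim probes, averaging of probes, a replicate block, moderation, deposited values, a ratio threshold and each array left out. A time left with 1 array was assumed to vary like the other times. Centring on spike-ins was not run, because the stated spike-in ratios were not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.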

Results

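Gene expression was measured in Debaryomyces hansenii, a salt-tolerant yeast, after 0.5, 3 and 6 h in 2 M NaCl. Each of 6 Agilent 2-colour arrays compared the RNA of stressed cells with that of control cells collected at time 0. No untreated cells of a later time were on the arrays. Each ratio therefore holds any change with time in culture as well as any change from the salt, and these cannot be told apart. Every time was covered by 2 arrays made from different biological replicates with the dyes exchanged, so that the stressed RNA carried Cy5 in replicate 1 and Cy3 in replicate 2. The array held 12640 probes for 6320 genes, 2 per gene. The array files described none of these genes by function, so the loci are given by locus name, and 5348 of the 6320 genes had one in the reference table. Of the probes, between 76.4% and 91.9% were well above background in the stressed channel and between 62.4% and 93.4% in the control channel. The median spot signal of the stressed channel ranged from 135 to 307. With 2 arrays per time, the number of arrays limits the precision of every ratio.

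The 2 probes of a gene gave similar ratios on each array, with correlations across genes between 0.81 and 0.94. The 2 arrays of a time, which shared neither RNA nor dye orientation, correlated across genes with r = 0.45 at 0.5 h, r = 0.60 at 3 h and r = 0.70 at 6 h. Genes are not independent replicates, so no p-value was attached to these correlations. The part of the response shared by both arrays of a time had a SD across genes of 0.24 on the log2 scale at 0.5 h. It was 0.41 at 3 h and 0.43 at 6 h, and with 2 arrays per time these SDs were not tested against each other.

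**Figure D1:**
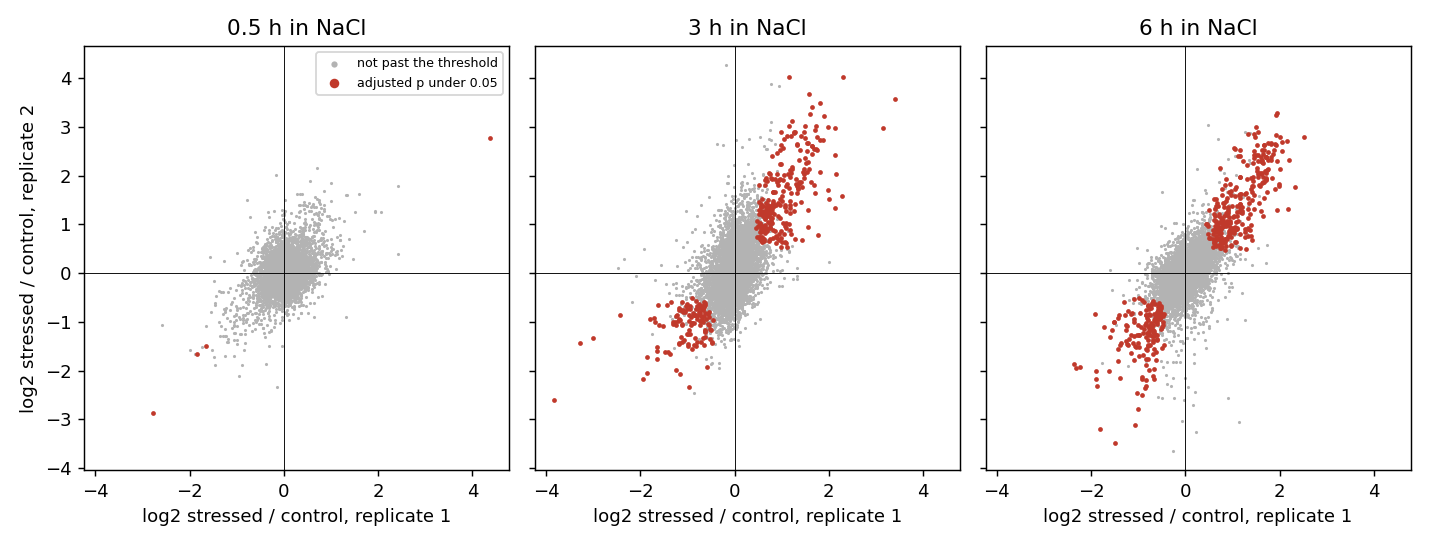
Log2 ratio of stressed over control signal for each of 5966 genes on replicate 1 (horizontal axis) and replicate 2 (vertical axis) at 0.5, 3 and 6 h in NaCl. Red points are the genes past an adjusted p of 0.05 in limma, 4 at 0.5 h, 367 at 3 h and 434 at 6 h.

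The first comparison asked which transcripts had changed 0.5 h after the salt was added. The locus DEHA2E05148g rose by 3.57 ± 1.12 on the log2 scale (SD, n = 2), which is 11.9-fold, with an adjusted p of 0.00899 in limma. DEHA2E14234g had a log2 ratio of -2.82 ± 0.07 (SD, n = 2) and an adjusted p of 0.00142, so that its level fell 7.07-fold. The loci DEHA2E01166g and DEHA2E21582g fell as well, with log2 ratios of -1.75 ± 0.13 and -1.57 ± 0.11 (SD, n = 2). These 4 of the 5966 genes tested passed the threshold, 1 higher and 3 lower, and the second probe of each moved the same way. With a replicate block, the same split as dye orientation, 60 genes passed, 32 higher and 28 lower, these 4 among them. A further look without the correction for multiple testing gave 507 genes at an unadjusted p under 0.05, or 8.50% of those tested. No gene passed without the 0.5 h array of replicate 1, and 1 passed without that of replicate 2, although the log2 ratio of DEHA2E14234g was -2.87 and -2.78 in those fits. The count was 20 without either 3 h array, 14 without either 6 h array, 1 with no background correction or with the deposited values, and 2 with the scanner software's processed signals, while centring on the median without loess gave 5 higher and 1 lower. Of the 18 alternative settings, the call ended in 2 for DEHA2E14234g, in 3 for DEHA2E05148g and in 7 each for DEHA2E01166g and DEHA2E21582g. Here and in later tallies, the settings are not 18 separate checks. Aquantile, a normalization of brightness between arrays, leaves the ratios unchanged. For a time not compared, leaving out its replicate 1 or its replicate 2 gives the same result.

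At 3 h DEHA2G17820g rose by 3.49 ± 0.11 on the log2 scale (SD, n = 2), or 11.2-fold, with an adjusted p of 0.00377 in limma. The second probe of this gene gave a smaller log2 ratio of 1.78. DEHA2G18964g and DEHA2C11528g rose by 3.16 ± 1.23 and 3.06 ± 0.13, and the second probe of DEHA2C11528g gave 1.97. DEHA2A03498g, DEHA2F02662g and DEHA2C04048g followed with log2 ratios of 2.65 ± 1.20, 2.63 ± 1.47 and 2.59 ± 2.02. Among called genes with a locus name, the lowest log2 ratio belonged to DEHA2G18348g, at -3.22 ± 0.86 (SD, n = 2), which is 9.30-fold lower. DEHA2G21032g, DEHA2C03828g and DEHA2A06314g fell as well, with log2 ratios of -2.36 ± 1.32, -2.17 ± 1.18 and -2.06 ± 0.16. DEHA2E01166g was again among the lowest, at -1.95 ± 0.14, and DEHA2F22374g had a log2 ratio of -1.79 ± 0.10.

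In all, 367 genes passed the threshold at 3 h, 243 higher with a median log2 ratio of 1.21 and 124 lower with a median of -0.95. All 367 had the same sign on both arrays, and 366 had the same sign with the gene's other probe. The calls were selected on these same arrays, so agreement in sign between the arrays is no separate support. The other probe read the same RNA. With a replicate block 822 passed, 511 higher and 311 lower, these 367 among them. Of the 367, 210 changed at least by a log2 ratio of 1. The number of calls was 936 without replicate 1 and 53 without replicate 2 of this time, and 143 without either 0.5 h array. Of the 12 loci named above, 2 were still past the threshold with the deposited values, 3 without replicate 2 of 3 h, 4 with no background correction, 5 without either 0.5 h array and 7 with the processed signals or with a trended and robust moderation. The call of DEHA2C04048g, with an adjusted p of 0.0498 in limma, ended in 11 of the 18 settings, and that of DEHA2G17820g in 0. Calls numbered 107 with no background correction, 108 with the processed signals, 44 with the deposited values and 91 with a trended and robust moderation, and centring on the median without loess gave 142 higher and 116 lower.

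At 6 h DEHA2C03476g had the highest log2 ratio among called genes with a locus name. It was 2.66 ± 0.20 (SD, n = 2), or 6.31-fold, with an adjusted p of 0.00171 in limma. DEHA2C07370g rose by 2.61 ± 0.95 and DEHA2G18964g by 2.58 ± 0.93. DEHA2F09614g, DEHA2D08558g and DEHA2B06864g rose by 2.43 ± 0.40, 2.40 ± 0.55 and 2.38 ± 0.63. The probe used for DEHA2F09614g shares 54 bases with a probe of another gene, and its second probe at least 50, so its ratio is uncertain. DEHA2F27104g and DEHA2C03828g had the lowest log2 ratios among called genes with a locus name, -2.50 ± 0.98 and -2.49 ± 1.42 (SD, n = 2). DEHA2E01166g, DEHA2E21582g, DEHA2G19602g and DEHA2F24860g lay between -2.14 and -2.08 with SDs from 0.22 to 0.35.

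A total of 434 genes passed the threshold at 6 h, 271 higher with a median log2 ratio of 1.18 and 163 lower with a median of -1.01. Of these, 433 had the same sign on both arrays, which selection on the same arrays favours, and 256 changed by a log2 ratio of at least 1. With a replicate block 755 passed, 422 higher and 333 lower, these 434 among them. Without replicate 2 of this time 11 genes passed, and 5 of the 12 loci named above were among them, while 203 passed without replicate 1. The count was 218 without either 0.5 h array and 723 without either 3 h array. It was 275 with no background correction, 233 with the processed signals, 236 with the deposited values and 12 with a trended and robust moderation, where 2 of the 12 named loci were still past the threshold, and centring on the median without loess gave 415 higher and 53 lower. The call of DEHA2D08558g ended in 7 of 18 settings and that of DEHA2C03828g in 6, among them the deposited values (adjusted p 0.0979 and 0.0636 in limma) and either 0.5 h array left out (0.0543 and 0.0616). Without replicate 1 of 6 h the call of DEHA2D08558g ended as well (0.0874).

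**Figure D2:**
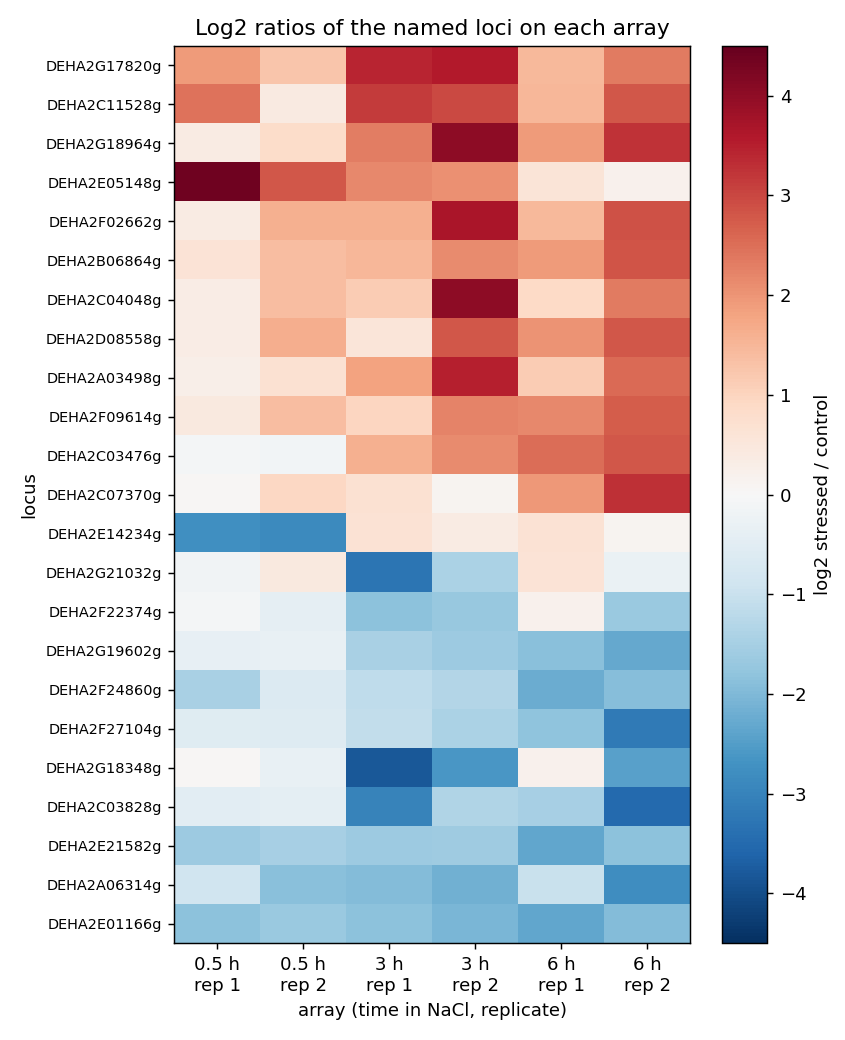
Log2 ratio of stressed over control signal (colour) of the 23 loci named for a time or for a difference that passed the threshold (rows) on each of the 6 arrays (columns, by time in NaCl and replicate). DEHA2E14234g is low on both 0.5 h arrays and near or above 0 on the other arrays, and DEHA2E01166g is low on all 6.

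The differences between times were tested within the same fit. DEHA2E14234g was higher at 3 h than at 0.5 h by 3.33 ± 0.24 on the log2 scale (SE, 2 arrays per time), with an adjusted p of 0.00560 in limma, and higher at 6 h than at 0.5 h by 3.22 ± 0.24. Its log2 ratios against the control at 3 and 6 h were 0.51 and 0.39, with adjusted p-values of 0.112 and 0.224 that did not pass. DEHA2C03476g was higher at 6 h than at 0.5 h by 2.76 ± 0.25 (SE) with an adjusted p of 0.0133. Its log2 ratio was -0.10 at 0.5 h, 1.86 at 3 h and 2.66 at 6 h. DEHA2E14234g was the 1 gene called between 0.5 h and 3 h, and with DEHA2C03476g it made the 2 called between 0.5 h and 6 h. With a replicate block 11 genes passed between 0.5 h and 3 h and 5 between 0.5 h and 6 h. The call of DEHA2E14234g between 0.5 h and 3 h ended without the 0.5 h array of replicate 1 (log2 difference 3.38, adjusted p 0.197) or replicate 2 (3.29, 0.233), with the processed signals (3.55, 0.117), with the deposited values (3.07, 0.135) and with centring on the median (2.37, 0.0618). For that difference 14 genes passed without replicate 1 of 3 h, 7 without replicate 2 and 9 with a trended and robust moderation.

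Between 0.5 h and 6 h, the call of DEHA2E14234g ended without replicate 1 or 2 of 0.5 h (adjusted p 0.244 and 0.145), without replicate 1 of 6 h (2.96, 0.0595), with the processed signals (3.44, 0.0732) and with the deposited values (3.06, 0.116). That of DEHA2C03476g ended without replicate 1 or 2 of 0.5 h (adjusted p 0.265 in each), without replicate 1 (2.90, 0.0595) or replicate 2 of 6 h (2.61, 0.183), with no background correction (2.39, 0.169), with the mean over probes (2.67, 0.0856), with a trended and robust moderation (0.168) and with the deposited values (2.34, 0.203). The 1 gene that passed without replicate 2 of 0.5 h was neither of these loci.

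Between 3 h and 6 h limma called 0 genes, with 577 genes (9.67% of those tested) at an unadjusted p under 0.05. Among genes with a locus name, the highest 6 h over 3 h differences by moderated statistic did not pass. They were those of DEHA2G03322g, DEHA2F12804g, DEHA2E20658g and DEHA2E06908g, at 1.93, 1.45, 1.40 and 1.91. The lowest differences were those of DEHA2E18568g, DEHA2D10076g, DEHA2C07216g and DEHA2G03740g, at -1.91, -1.90, -1.42 and -1.61. The adjusted p-values of all these loci ran from 0.215 to 0.433. The second probe of DEHA2E18568g gave log2 ratios of -1.09 at 3 h and -1.26 at 6 h, so its fall was nearly absent there. For the other lowest loci, in that order, the second probes gave 0.50, 0.05 and 0.19 at 3 h. At 6 h they gave -0.63, -0.77 and -0.40, also smaller falls. The second probes of the highest loci rose as well. Without replicate 1 of 3 h 1 gene passed, and with a trended and robust moderation 4 genes passed.

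Averaged over the 3 times, 1151 genes differed from the control, 651 higher and 500 lower, and 173 of them had a mean log2 ratio of at least 1 in size. The median of the called genes was 0.56 among the higher and -0.48 among the lower. The fit took the 6 arrays as independent, but deviations of same-numbered arrays correlated across genes at 0.19, 0.31 and 0.37. A shared culture or control would make the SE of this mean too small and the count too high. A dye bias would cancel in the mean. With a replicate block, which takes up the difference between replicates, 1624 genes passed. The block also takes that difference out of the error. It therefore does not correct for a shared culture or control, and the larger count is not a corrected one. The loci called at each of the 3 times were DEHA2E01166g and DEHA2E21582g, both lower, and they are named here after their values were seen. At 0.5 h both calls ended with no background correction, processed signals, median centring, deposited values and either 0.5 h array left out, and with a trended and robust moderation (adjusted p 0.766 and 0.740 in limma). With that moderation the calls at 3 h and 6 h ended as well, for DEHA2E01166g (0.131 and 0.118) and for DEHA2E21582g (0.141 and 0.0811). Centring on the median without loess gave 668 higher and 221 lower. The count fell to between 403 and 415 without either 0.5 h array or replicate 2 of 6 h, was 761 without replicate 1 of 6 h and 758 without replicate 2 of 3 h.

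Calls were also compared between times. At both 3 h and 6 h 135 genes were higher, against 11 for independent lists of these sizes, and 58 were lower, against 3.39. Genes simulated as unchanged, as if the arrays of a replicate had 1 control, gave 0 in each direction. Unchanged genes give nearly no calls, so this value does not show how much of the excess over independent lists comes from shared controls, and part of it may. Arrays of different times and different replicates shared no RNA, and their log2 ratios had a mean covariance of 0.07 between 0.5 h and 3 h, 0.14 between 3 h and 6 h and 0.08 between 0.5 h and 6 h. The simulated covariances were 4.67e-05, 0.000478 and 0.000763. They are small by construction, since the simulated genes had no change in common, so they are no test of the observed values.

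Spike-in transcripts, added to the RNA in known mixtures, were measured on each array with 20 spots per transcript. On 5 arrays the means of the 10 transcripts spanned between 3.18 and 4.18 on the log2 scale of red over green. On the 3 h array of replicate 1 they spanned 1.66. The scanner software's log ratios spanned 2.48 on that array and between 5.55 and 6.55 on the others.

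**Figure D3:**
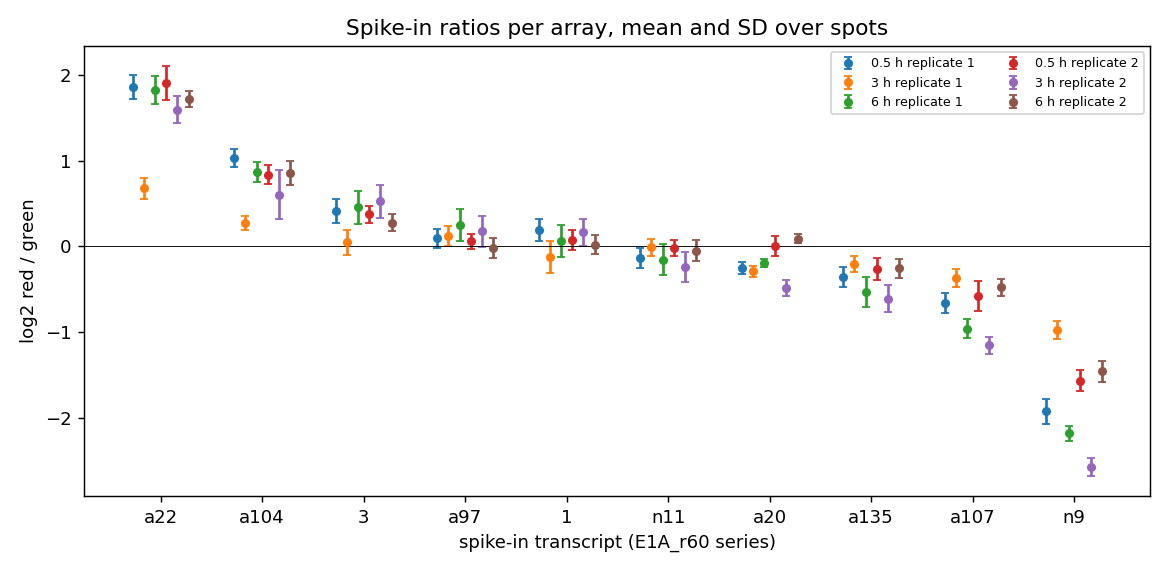
Log2 ratio of red over green signal of the 10 spike-in transcripts on each of the 6 arrays, as mean and SD (bars) over 20 spots. The points of the 3 h array of replicate 1 span 1.66, less than those of the other arrays.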

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

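The tests of the spike-in ratios and the count over turned signs were chosen after the results were seen, and the bound that would have excluded compression of all ratios was replaced after its value was seen. A test for values far from the rest was applied to 10 measures over the 6 arrays, and chance gives such a value in about 1 of 20 tests. It marked 3 measures. On the 3 h array of replicate 2, 93.4% of the probes were well above background in the control channel, more than on any other array. This measure mixes dyes, since the control was in Cy3 on replicate 1 and in Cy5 on replicate 2. Over all Cy5 channels the share ran from 62.4% to 93.4%. It was 91.9% for the stressed RNA on the 6 h array of replicate 1, so 93.4% does not stand apart among them.

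On the 3 h array of replicate 1 the slope of observed against stated spike-in log ratios, as the scanner software gives it, was 0.295, while the other arrays lay between 0.788 and 0.926, and the median red signal of its negative controls was 113.5, above the other arrays. A higher background on that array may reduce such ratios, but after subtracting each array's negative-control median its spike-in log2 ratios spanned 2.39, against 5.36 or more elsewhere, which argues against background as the whole cause. Whether all ratios on that array are compressed stays open, and a cause in the spike-ins themselves was not tested. The bound set first, a SD within the range of the other 5 arrays, was met and would have argued against compression, but it ignored that times differ in response: the SD of its gene log2 ratios was 0.417, above the lowest of the other arrays and below the 0.663 of the other 3 h array, which comes from other RNA. No biological explanation was tested, since spike-ins are added after the cells are harvested.

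The log2 ratio to the time-0 control differed between times, by a test of the difference, for 2 loci. For DEHA2E14234g the difference was 3.33 from 0.5 h to 3 h and 3.22 from 0.5 h to 6 h. For DEHA2C03476g it was 2.76 from 0.5 h to 6 h. Without untreated cells at these times, an effect of the salt cannot be told from one of time in culture. The calls of DEHA2E14234g ended in 5 of 18 alternative settings for each difference and that of DEHA2C03476g in 8 of 17, either 0.5 h array left out among them. As stated for 0.5 h, some of these settings repeat others or the main fit.

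The count of genes changed on average was recomputed with the sign of a whole replicate turned, since arrays of a replicate can share a control and cannot be turned one by one. This leaves 2 patterns, too few for a share under 0.05. The real pattern gave 1151 genes and the other 0, so 1 of the 2 reached the real count.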

How the results depend on the processing

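The alternative that leaves out genes with a matching probe was chosen after seeing the data, and whether replicate numbers pair the arrays was weighed after the counts with a replicate block, an alternative fixed beforehand, were seen. No named value changed direction under any alternative that was run. Counts stayed within 1.5 times for mean signals, no filter on dim probes and genes with matching probes left out. Aquantile, a normalization of brightness between arrays, leaves the ratios unchanged. Its counts therefore equal those of the main fit by construction and are no check of them. The cause of the changes below was not tested. Counts are given for 0.5 h, 3 h and 6 h, and then for differences between times. With no background correction they were 1, 107 and 275, and 1 between 0.5 h and 6 h. With processed signals they were 2, 108 and 233, then 0 between 0.5 h and 3 h and 1 between 0.5 h and 6 h. With deposited values they were 1, 44 and 236, then 0 and 0. With a trended and robust moderation they were 91 at 3 h and 12 at 6 h, 9 between 0.5 h and 3 h and 4 between 3 h and 6 h. Median centring gave 0 between 0.5 h and 3 h and a median over all genes of 0.12 between 3 h and 6 h, against -0.03. Only bright probes, and likewise the mean over probes, gave 1 between 0.5 h and 6 h. A log2 ratio of at least 1 as a second threshold left 210 at 3 h, 256 at 6 h and 173 on average, and 27 genes lower at both 3 h and 6 h.

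With a replicate block, the same split as dye orientation, counts were 60, 822 and 755 for the 3 times, 11, 0 and 5 for the differences from 0.5 h to 3 h, 3 h to 6 h and 0.5 h to 6 h, and 1624 on average. Leaving out each array in turn gave 0 to 20 genes at 0.5 h, 53 to 936 at 3 h and 11 to 723 at 6 h. It gave 0 to 14 between 0.5 h and 3 h, 0 to 1 between 3 h and 6 h, 0 to 2 between 0.5 h and 6 h and 403 to 1675 on average. Of 60 spike-in means, 47 moved by more than their SD with the scanner's log ratios. Spike-in centring, the slide block and all list tests were not run. Signal over background limits ratios of dim genes, whose ratios may be compressed, which was not tested.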

Other observations

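The tests of runs, of distances between loci and of chromosome ends were chosen after the pattern was seen, the window of 10 loci after several had been looked at; the tests of neighbours across replicates, without matching probes and on ranks were set before their results, with the pattern already seen. Runs of neighbouring loci changed in the same direction. The longest run of loci called on average over the 3 times reached from DEHA2C13288g to DEHA2C13420g, 7 loci that were all lower, with mean log2 ratios from -1.21 to -0.48. Runs of 4 higher loci lay from DEHA2E14498g to DEHA2E14564g, from DEHA2F08228g to DEHA2F08294g, from DEHA2G15400g to DEHA2G15466g and from DEHA2C10934g to DEHA2C11000g. The 3 loci from DEHA2D08514g to DEHA2D08558g were higher by 1.39 to 1.68. There were 19 runs of 3 or more, against a median of 7 and at most 17 in 2000 permutations of the loci within chromosomes.

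Across 4330 pairs of adjacent measured loci, the mean log2 ratios over the 3 times correlated at r = 0.13, with a one-sided permutation p of 1e-05, the smallest that 100000 permutations can give. The correlation was 0.053 at a distance of 2 loci, 0.028 at 3, 0.0033 at 5 and 0.021 at 10. A dye or slide artefact fixed to a locus would turn sign with the dye exchange, yet a locus on 1 replicate correlated with its neighbour on the other at 0.059 or more at each time. On ranks the correlation was 0.129, which argues against a few strong loci. Without loci that have a matching probe it was 0.125 over 4253 pairs. That argues only against cross-hybridization between probes with at least 50 identical bases. Loci with shorter matches stayed in, and similarity outside the probes was not tested, so cross-hybridization of other similar neighbours stays open. No biological explanation was tested, nor were transcripts that run into the next locus.

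Measured loci within 10 of a chromosome end were lower than the rest by a mean log2 difference of -0.20 over 77 loci. The one-sided p from circular shifts within chromosomes was 9e-05. End loci that were not measured or not matched by name were left out, so the 77 do not cover every locus there. The difference was -0.13 at 0.5 h, -0.26 at 3 h and -0.23 at 6 h. Similar end loci could share signal, but without loci that have a matching probe the difference was -0.178 over 59 loci, with a p of 0.00085. Shorter matches between probes and similarity outside the probes were not tested.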
